A study of Danio rerio with 24 samples.

How the data were processed

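The samples were brain with pituitary and skin of 6 transgenic zebrafish that overexpress ASIP and 6 wild-type controls, after 30 days of acclimation per the labels' protocols. Per the labels, 150 ng of total RNA of each sample was labelled with Cy3 and each sample was hybridised to its own array, on 6 slides of 4 arrays. The submitters' processing notes name Agilent Feature Extraction 11.5.1.1, which is also the version in the file headers. The deposited scanner files hold the spot intensity after background subtraction and detrending within the array, per the file headers, with no scaling between arrays. They also hold median spot and local background intensity and flags for spots well above background, non-uniform or saturated. A deposited value table of the same arrays holds the authors' processed values, which the comparison with the scanner signals showed to be log2 values in the same direction, centred per probe within a tissue. The steps behind that table are not given in the sources used here.

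The main values were log2 of the processed signal minus the array's 75th percentile of it, over 43776 non-control probes with 1 spot each. Non-uniform spots, 214 over all arrays and at most 24 on one, were left out. A probe was tested in a tissue when it was well above background on at least 5 of the 6 arrays of one genotype. Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), transgenic minus control, with 12 arrays and no covariate. An adjusted p under 0.05 after the Benjamini-Hochberg adjustment over all tested probes counted as changed. The difference between tissues was a contrast over 4 groups and 24 arrays, on probes tested in both tissues. All p-values are two-sided, and those within a tissue measure the spread between fish. Those of the difference between tissues took the 24 arrays as independent, though brain and skin share fish. Which fish were male is not given in the sources used here, so sex was not a covariate.

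A probe not well above background on any array of a group has only a bound there. Its difference is given as at least N-fold, from the mean of the bright group against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background on that array. The same bound is given for the named probes that 1 or 2 of the 6 arrays of a group measured. Fitted log2 differences of such probes are not bounds, and the bounds apply to the scaled signals with no offset added. The ratio is over the normalized log2 values.

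The rule fixed before the data were examined took genes with a symbol, more per comparison than are named here, and could not be used. The files do not pair the probe IDs, of which 29806 begin with Dr#E and 13970 with Dr#S, with gene names, and 0 of them matched an ID in the reference tables used here. So the 2 probes with the largest rise and the 2 with the largest fall among the changed probes were named per tissue and for both tissues together, by the fitted log2 difference, which for both tissues was the smaller of the pair in absolute size. For the difference between tissues the probes with the smallest p were named. The analyses that need gene names were not run. These are asip1 itself, the gene lists and markers of cell types, the share of changed genes per chromosome, and counts of genes in place of probes.

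Brain and skin share fish by their labels, which pairs them across tissues. In each of the 12 fish, the deviations from the group means correlated more between its own brain and skin (r from 0.181 to 0.491, across probes) than with any other fish of the group. The fit of the difference between tissues was therefore repeated with fish as a replicate block. Control and transgenic fish share 4 numbers, which mark different animals. The correlations of same-numbered fish across genotypes ran from -0.254 to 0.0968, and none was best with its own number. That check and a block by number are described with the alternatives.

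The arrays were scanned on 2 days, and slide and scan day were tested as batches. The other alternatives were quantile normalization, scaling to the median, and normexp background correction with an offset of 50 on the median spot signal and median background, since the mean signal is not among the columns used. Further ones were the authors' values, all probes or only those well above background on every array, non-uniform spots kept, slide as a random block (duplicateCorrelation) or fixed term, trend and robust eBayes, array weights, one fit of all arrays, other thresholds, and leaving out each fish. Scan day as a term, the fit of the 8 arrays with shared numbers without a block, and some alternatives for the changes in both tissues were chosen after seeing the data.

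Of the authors' values, those of 43741 probes matched a probe of the scanner files, and 171774 values were empty. The column medians lay between 0.00483 and 0.0210. In control brain they were 0.0146 for fish 2, 0.0133 for fish 3, 0.0120 for fish 4, 0.0104 for fish 5, 0.0136 for fish 7 and 0.0109 for fish 8. In transgenic brain they were 0.00483 for fish 1, 0.00829 for fish 2, 0.0159 for fish 4, 0.00759 for fish 5, 0.0128 for fish 6 and 0.0185 for fish 7. In control skin they were 0.0153 for fish 2, 0.0193 for fish 3, 0.0127 for fish 4, 0.0210 for fish 5, 0.0126 for fish 7 and 0.00894 for fish 8. In transgenic skin they were 0.00957 for fish 1, 0.0111 for fish 2, 0.0102 for fish 4, 0.0124 for fish 5, 0.00980 for fish 6 and 0.0119 for fish 7. On probes brighter than the 75th percentile, deviations of the table from the probe mean followed those of the scanner values with slopes from 0.93 to 1.02 and r from 0.927 to 0.994. The slope of the genotype difference fell with the signal, to 0.334 in brain and 0.233 in skin on the dimmest detected probes, so the table understates the differences of dim probes relative to the scanner signals. Apart from the centring per probe within a tissue, the scaling between arrays and the reference of that table remain unknown.

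The fits were tested on simulated data, with the real fish's spread and 67, 67 and 66 probes changed by 0.5, 1 and 2 on the log2 scale. In brain, with 31710 probes, 14.9%, 55.2% and 95.5% of these were called, with 3 false calls. In skin, with 29842 probes, 11.9%, 38.8% and 84.8% were called, with 6 false calls. For the difference between tissues, with 26522 probes, the shares were 1.49%, 40.3% and 89.4%, with 9 false calls. The simulated spread was independent between probes and arrays, with no background floor. Far fewer probes were changed than in the real data, where 11.7% changed in brain and 32.3% in skin. The shares called therefore need not hold for the real fits. Each count of changed probes was also computed for 100 of the 462 groupings of the 12 fish into 6 and 6, the real one included, in which a fish's brain and skin moved together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.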

Results

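Transcript levels were measured in 2 tissues of 12 zebrafish, brain dissected with the pituitary, and skin. The 6 transgenic fish overexpressed agouti-signaling protein (ASIP), a secreted antagonist of melanocortin receptors known for its part in pigment patterning, and the 6 controls were wild-type fish of the Tu line. Per the series design each group held 3 males and 3 females. RNA of each tissue of each fish was labelled with Cy3 and hybridised alone, which gave 24 one-colour arrays in 4 groups of 6. Every array carried 43776 non-control probes. The share of probes well above background was 75.1% ± 4.67 in control brain, 73.5% ± 4.11 in transgenic brain, 69.1% ± 1.79 in control skin and 68.6% ± 2.03 in transgenic skin (SD, n = 6 each). No spot was saturated on any array. The 6 arrays per group limit the precision of every value given here. The files do not pair their probe IDs with gene names, so probes are reported by ID, and the asip1 transcript itself was not analysed here.

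**Figure D1:**
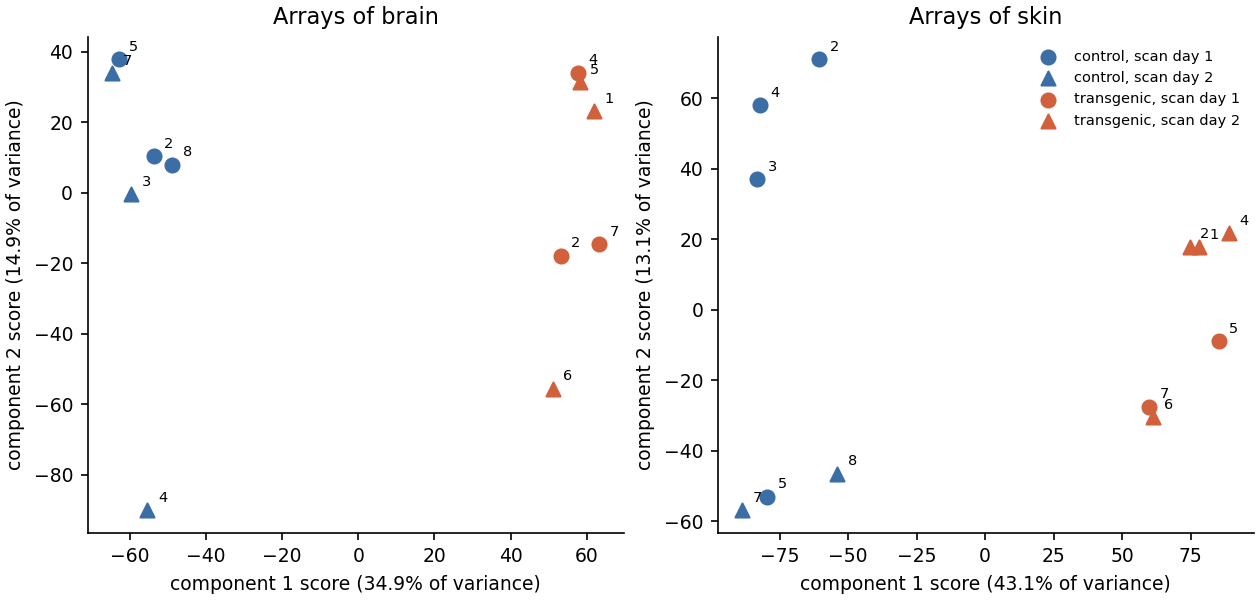
Scores of the 12 brain arrays (left) and the 12 skin arrays (right) on the first and second principal components of the scaled log2 signals of the tested probes, in arbitrary score units with the share of variance on each axis. Colour gives the genotype, symbol the scan day and the number beside a point the fish, and component 1, with 34.9% of the variance in brain and 43.1% in skin, separates the genotypes in both tissues.

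The genotype was the main axis along which the arrays of each tissue differed. In brain, component 1 held 34.9% of the variance, with control scores from -64.7 to -48.9 and transgenic scores from 51.1 to 63.3. In skin it held 43.1%, with control scores from -88.7 to -54 and transgenic scores from 59.9 to 89.1. Within brain, the correlation of scaled log2 signals between arrays of one group, across probes, ranged from 0.954 to 0.98, and within skin it ranged from 0.94 to 0.979. No pair of arrays held identical values.

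The first comparison was between the brain transcriptomes of transgenic and control fish. Each genotype was represented by 1 line, so the differences given here include any difference between the lines that does not stem from ASIP. Of 31710 probes tested in brain, 3717 (11.7%) differed between transgenic and control fish, of which 1753 rose and 1964 fell. The changes were mostly small by the fitted difference, with 1536 of the 3717 reaching 2-fold (725 up, 811 down) and 209 reaching 8-fold (103 up, 106 down). Of the 209, 104 had 1 genotype not well above background on any array, so their fitted sizes are not measured ones. The probe with the largest fitted rise, a rank set against background signal, was CUST_3609_PI428451958 (ID Dr#S12073214). It was well above background on all 6 transgenic brain arrays and on none of the 6 control arrays, and was at least 557-fold higher in transgenic brain (limma adjusted p = 1.19e-09). Its scaled log2 signal was 3.12 ± 0.62 in transgenic and -7.99 ± 0.58 in control brain (SD, n = 6 each). The next by fitted difference, CUST_17359_PI428451953 (Dr#E00000125856), was also not well above background on any control brain array, at -0.06 ± 0.60 against -8.27 ± 0.63, at least 61.7-fold higher (limma adjusted p = 1.11e-08). Among the falls, CUST_19998_PI428451953 (Dr#E00000136985) went from 1.14 ± 0.15 in control brain to -6.82 ± 1.42 in transgenic brain, where 1 of 6 arrays, that of fish 4, measured it well above background. It was at least 117-fold lower in transgenic brain (limma adjusted p = 9.4e-07), and at least 121-fold lower without fish 4. CUST_12520_PI428451958 (Dr#S41573980) was not well above background on any transgenic brain array and on 5 of 6 control arrays was. Its mean was at least 51.8-fold lower in transgenic brain (limma adjusted p = 0.003). Control fish 8 was the exception, with a scaled log2 signal of -7.53, and without it the mean was at least 145-fold lower in transgenic brain.

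The brain test was limma's moderated test on 6 against 6 fish, with Benjamini-Hochberg adjustment over all tested probes. An unadjusted p under 0.05 was found for 8058 probes, where 1585.5 would be so by chance. The 6 control and 6 transgenic values did not overlap for 2180 probes (6.87%), against 0.216% by chance. Brain arrays of each genotype were spread evenly over both scan days. With scan day as a fixed term the count was 4251, and within the days, with 3 against 3 fish, it was 870 on day 1 and 752 on day 2. Of the 870 probes, 854 had the same sign on day 2, and of the 752, 739 had the same sign on day 1. With slide as a fixed term 2003 probes changed. Each slide held 2 arrays of a tissue, too few for a fit within a slide.

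**Figure D2:**
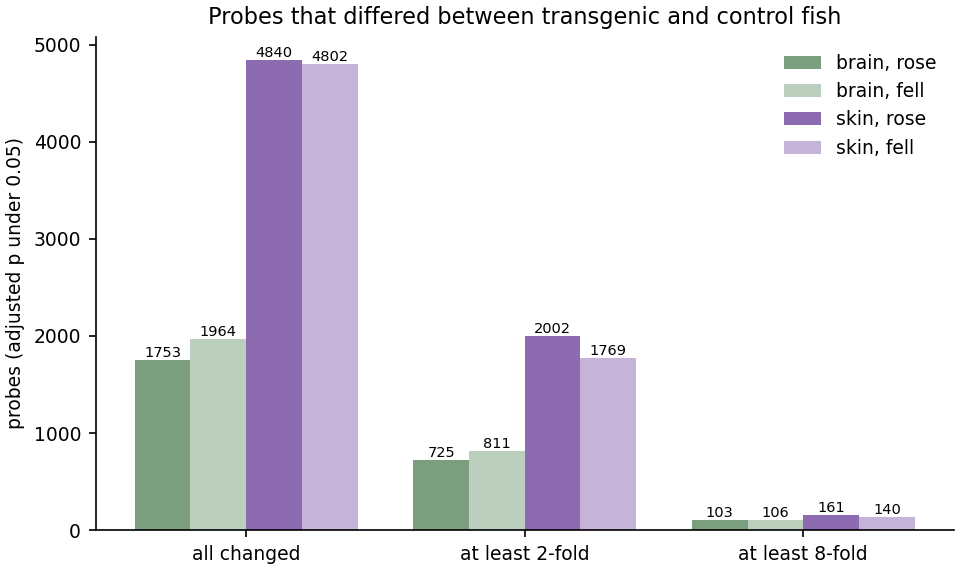
Number of probes with an adjusted p under 0.05 between transgenic and control fish, by tissue, direction and size of the change (6 fish per group, linear axis from 0). In skin 4840 probes rose and 4802 fell, and in brain 1753 rose and 1964 fell.

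The second comparison was the same one in skin. Of 29842 probes tested in skin, 9642 (32.3%) differed between transgenic and control fish, 4840 up and 4802 down. Of these, 3771 reached 2-fold (2002 up, 1769 down) and 301 reached 8-fold (161 up, 140 down) by the fitted difference. Of the 301, 110 had 1 genotype not well above background on any array. CUST_3609_PI428451958 had the largest fitted rise in skin too, again against controls at background. It was at least 3006-fold higher in transgenic skin (limma adjusted p = 2.87e-11), with a scaled log2 signal of 5.97 ± 0.38 on transgenic and -7.35 ± 0.68 on control arrays (SD, n = 6 each). CUST_11823_PI428451953 (Dr#E00000121450) followed at 3.66 ± 0.53 against -7.69 ± 0.26, at least 604.8-fold higher (limma adjusted p = 1.97e-11). The falls with the largest fitted differences were those of CUST_8335_PI428451953 (Dr#E00000059321) and CUST_2667_PI428451958 (Dr#S24430385), which were among the bright probes of control skin at 6.68 ± 0.41 and 6.85 ± 0.41. In transgenic skin they were at -6.15 ± 2.45 and -5.64 ± 2.36. They were at least 2890-fold lower (limma adjusted p = 1.47e-06) and at least 3060-fold lower (limma adjusted p = 1.38e-06) in transgenic skin. Transgenic fish 1 kept the highest signal of its group for both, at -1.27 and -0.98. CUST_8335_PI428451953 was well above background on 1 of the 6 transgenic skin arrays and CUST_2667_PI428451958 on 2, that of fish 1 included in both cases. Without fish 1 the bounds were 4723-fold and 5151-fold.

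In skin an unadjusted p under 0.05 was found for 13020 probes against 1492.1 by chance. The genotypes did not overlap for 4244 probes (14.2%), against 0.216% by chance. Scan days were less even here, with 4 control and 2 transgenic skin arrays on day 1 and 2 control and 4 transgenic arrays on day 2. With scan day as a fixed term 9016 probes changed. Within the days 1477 probes changed on day 1, of which 1435 had the same sign on day 2, and 2707 changed on day 2, of which 2560 had the same sign on day 1. With slide as a fixed term the count was 5417.

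**Figure D3:**
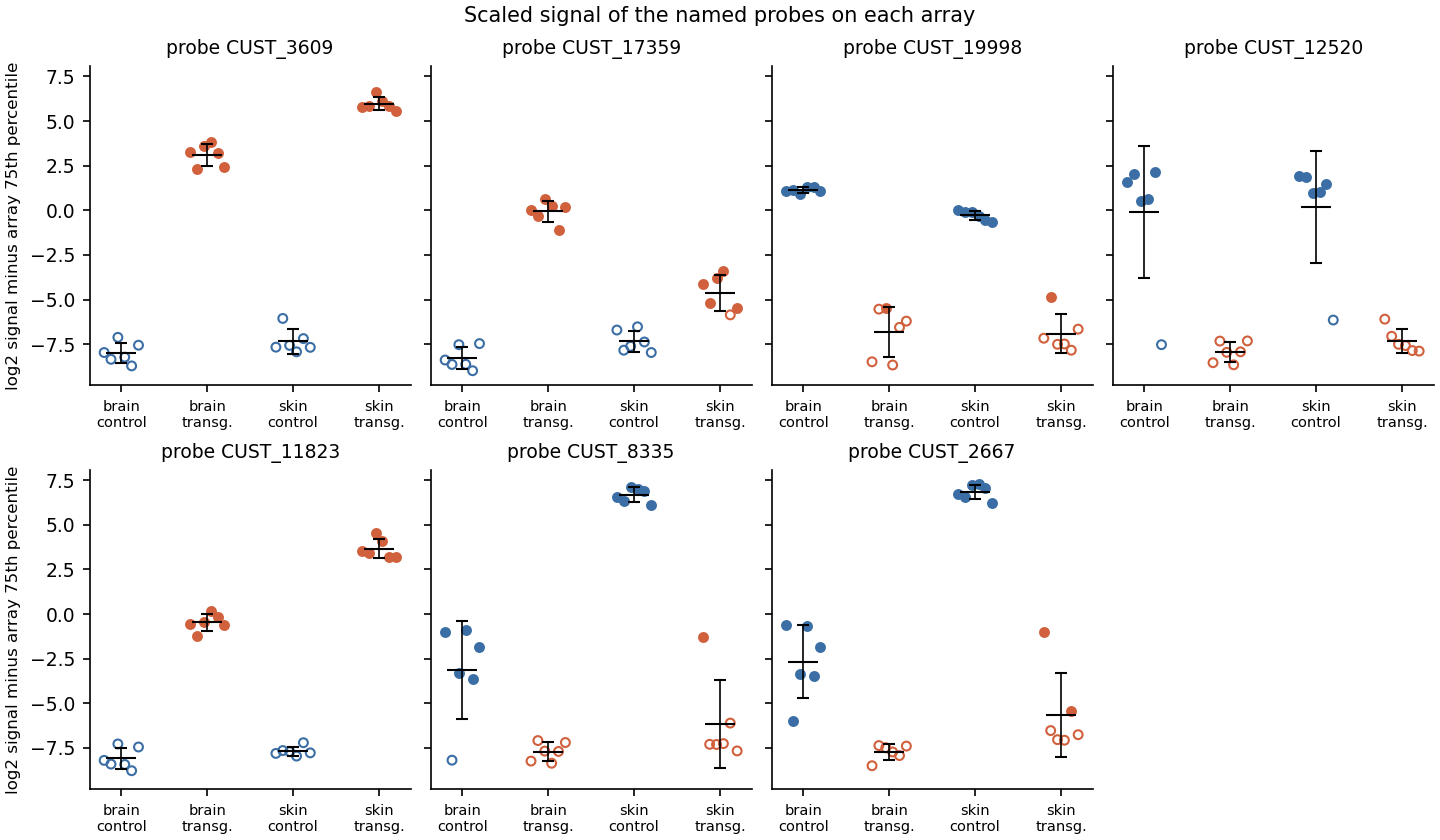
Log2 signal minus the 75th percentile of the array (vertical axis, log2 units) of the 7 probes named for brain and skin, by tissue and genotype. Points are arrays, filled where the probe was well above background and open where it was not, and bars give the mean and SD of 6 arrays. CUST_3609 is at 3.12 and 5.97 in transgenic brain and skin and below -6 on every control array.

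Most changed probes were detected in both tissues. In brain 3114 of 26522 such probes changed (11.7%), and 603 of the 5188 detected in brain alone did (11.6%). In skin 8549 of the 26522 changed (32.2%), and 1093 of the 3320 detected in skin alone did (32.9%).

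The third comparison asked whether the genotype difference itself differed between the tissues. It did for 3040 of the 26522 probes tested in both, by a limma contrast of the skin difference minus the brain difference over all 24 arrays. The contrast was positive for 1499 of them and negative for 1541. The skin difference was the larger in size for 2555 of the 3040 (84.0%), against 68.5% of all 26522 probes. Of the 3040, 2248 changed in skin and not in brain, 319 in brain and not in skin, 288 in both and 185 in neither. CUST_366_PI428451953 (Dr#E00000054735) rose in skin, by 3.58 on the log2 scale (SE 0.23), against a brain difference of -0.15 (SE 0.12), a contrast of 3.73 (limma adjusted p = 1.76e-08). It was dim in control skin, well above background on 5 of 6 arrays, and its skin difference was 1.06 with normexp background correction and 1.42 in the authors' values. CUST_6682_PI428451953 (Dr#E00000130568) was not well above background on any transgenic skin array and was at least 8.15-fold lower there than in control skin by the scaled signals, while its log2 difference with normexp background correction was -0.83. Its brain difference was -0.20 (SE 0.11), and the contrast had a limma adjusted p of 4.39e-08. Within scan days, 217 probes passed on day 1 and 532 on day 2. Without control fish 3 the count of 3040 fell to 1944.

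The last comparison asked which probes changed in both tissues. Of 26522 probes tested in both, 867 rose in brain and skin and 932 fell in both, where independent lists of these sizes would share 238.2 and 263.9. Another 82 changed in opposite directions, where independent lists would give 501.6. Since the tissues share fish, the lists are not independent. How much of the gap from independent lists stems from the shared fish was not tested. The 1799 probes that changed in one direction in both tissues were 57.8% of the 3114 brain changes among these probes, and a smaller share of the 8549 skin changes. Besides CUST_3609_PI428451958 and CUST_11823_PI428451953, which rose in both tissues, the probes with the largest shared falls, ranked by the smaller of their fitted log2 differences in brain and skin, were CUST_12520_PI428451958 and CUST_7693_PI428451958 (Dr#S24430451). CUST_7693_PI428451958 was well above background on all control arrays and on no transgenic array of either tissue, at least 50.5-fold lower in brain (limma adjusted p = 1.02e-07) and at least 43.5-fold lower in skin (limma adjusted p = 5.1e-10). Across all 26522 probes, which are not independent replicates, brain and skin log2 differences correlated with Pearson's r = 0.607 and Spearman's rho = 0.466. Brain and skin came from the same fish, and regrouping the fish at random gave a mean r of 0.44 with a highest value of 0.615, and at most 0.513 where the genotypes were mixed evenly.

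**Figure D4:**
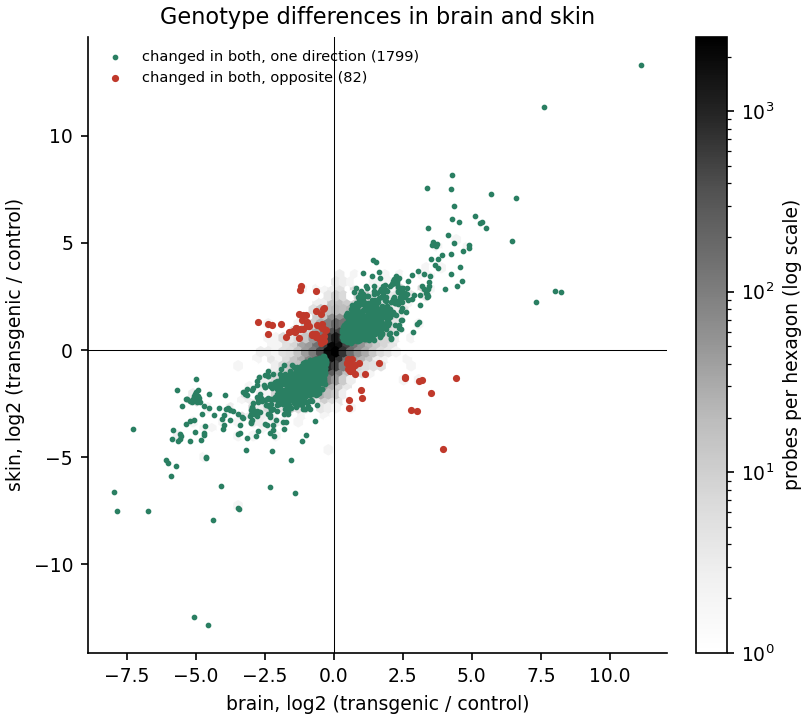
Log2 ratio of transgenic to control signal in skin (vertical axis) against that in brain (horizontal axis) for 26522 probes tested in both tissues. Grey hexagons give the number of probes on a log scale, green points are the 1799 probes changed in one direction in both tissues and red points the 82 changed in opposite directions.

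Some probes were well above background on every array of one genotype and on none of the other. In brain there were 102 such probes, 61 seen in controls and 41 in transgenic fish. In skin there were 148, with 77 in controls and 71 in transgenic fish. In 22 cases the probe was of this kind in both tissues, 12 in controls and 10 in transgenic fish, and in 0 cases was the genotype opposite. Of 64 such brain probes that were tested in skin, 57 changed there in the same direction (89.1%). Of 88 such skin probes tested in brain, 50 did (56.8%). The lower bound of the difference reached 4-fold for 67 of the 102 brain probes and 62 of the 148 skin probes.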

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

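The tests of spread, of scan day, of the size of the skin difference, of a difference between the fish lines and of the correlation between tissues were chosen after the result was seen. Those of the detection limit and the other regroupings of the fish were written before.

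The genotype difference differed between brain and skin for 3040 probes. It was the largest count among 100 of the 462 groupings of the 12 fish, of which the highest other gave 3. So 1 of 100 reached it, the lowest share that 100 groupings can give. Mixing the genotypes puts their differences into the spread of a grouping and lowers its count. The regroupings therefore do not test a difference between tissues apart from the genotype differences within them. The changes within tissues were also the largest counts, at 1 of 100 each. Brain gave 3717 against a highest other of 8 and skin 9642 against 2021. For changes in both tissues 1 of 100 reached the count, 1799 against a highest other of 2, but 94 of the 99 other groupings changed 0 brain probes and so had none to share. That count says nothing on agreement between tissues beyond the counts within them. The skin grouping with 2021 exchanged 1 fish of each genotype, and the next highest gave 30. The correlation of 0.607 between brain and skin differences was reached by 2 of 100 groupings, the real one included. The other that reached it, at 0.615, exchanged 1 fish of each genotype. The mean of the others was 0.44, and the 44 groupings that mixed the genotypes evenly gave a mean of 0.36 and at most 0.513, so part of the correlation arose without the genotype.

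Of the probes named for the difference between tissues, the skin difference minus the brain difference was 3.73 for CUST_366_PI428451953 and 3.91 for CUST_23803_PI428451953 (Dr#E00000036318). It was -4.29 for CUST_6682_PI428451953 and -4.60 for CUST_6681_PI428451953 (Dr#E00000039851), all on the log2 scale. The last pair had similar signals to each other wherever they were well above background, so these falls are not independent cases. CUST_23803_PI428451953 was not well above background on any control skin array, nor the last pair on any transgenic skin array, so these 3 values are set against background signal and are neither measured differences nor bounds. CUST_23803_PI428451953 rose in both tissues, by 4.27 (SE 0.22) in brain and at least 71.1-fold in skin, and its contrast between tissues did not pass with normexp background correction (0.15) or the authors' values (0.59).

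More probes changed in skin than in brain, 9642 against 3717. A lower spread in skin would show as a lower residual SD, but the median over tested probes was 0.365 in skin and 0.311 in brain. With scan day as a fixed term 9016 skin probes and 4251 brain probes changed, so the uneven scan days of skin do not account for the gap. Over the 26522 probes tested in both tissues, the median absolute log2 difference was 0.377 in skin and 0.197 in brain. By this gap of 0.181 the fitted differences were larger in skin. It comes from the same signals as the counts, so it is no separate support for a cause. The highest of the 99 other groupings of the fish gave 0.178, and the 44 that mixed the genotypes evenly at most 0.0702. Another measure, the share of these probes with the larger difference in skin, was 68.5%, with at most 66.2% in the evenly mixed groupings, but 3 groupings with 1 or 2 fish of each genotype exchanged gave as much, up to 71.3%. A difference in the cell types within the dissected skin could also give more changes there and was not tested, since the probes have no gene names here.

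Probes seen on all arrays of one genotype and on none of the other numbered 102 in brain and 148 in skin. In brain 1 other grouping gave 180. It was the grouping that parted the 6 brain arrays with the fewest probes well above background, at most 73.7%, from the others, at least 76.6%, and 0 of its 180 probes reached a 4-fold bound. Counting only probes with a bound of at least 4-fold, the real grouping gave 67 in brain and 62 in skin and every other at most 3. Exchanging fish breaks the pattern of any probe that follows the genotype. Low counts in the other groupings were therefore likely from the outset and do not exclude a detection limit. For these 67 and 62 probes the bound itself sets the difference from the floor at 4-fold or more. The rest of the 102 and 148 have smaller bounds and may lie near the detection limit. Grouping by scan day gave 4 probes in brain and 7 in skin. Of such probes tested in both tissues 88.5% differed in the same direction in both. Brain and skin came from the same fish, and the same probes gave a mean of 57.6% and at most 67.7% over the 44 groupings that mixed the genotypes evenly, and 88.5% in 1 grouping with 1 fish of each genotype exchanged. The probes were picked by the real grouping, so their shares in other groupings are no test of the 88.5%. A fixed difference between the lines and a response to the transgene in both tissues would each give a high share, so they cannot be told apart, as the design has 1 line per genotype.

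Single fish stood apart from the rest of their group in 10 of 64 sets of 6 values, where chance gives about 1 in 20, or 3.2. In 15 of the 64 sets no array was well above background for the probe, and of the other 49 sets 8 stood out, where chance gives 2.45. For CUST_12520_PI428451958 control fish 8 was the lowest in both tissues, at -7.53 in brain (nearest 0.50) and -6.15 in skin (nearest 0.95). Transgenic fish 1 was the highest in skin for CUST_8335_PI428451953 at -1.27 (nearest -6.11) and for CUST_2667_PI428451958 at -0.98 (nearest -5.44). These 2 probes also had similar signals to each other on each control skin array, so the 2 cases are not independent. The chance counts take all sets as independent and the probes as not picked for their differences. In skin, control fish 4 was lowest for CUST_366_PI428451953 at -5.67, control fish 7 highest for CUST_23803_PI428451953 at -7.11 and transgenic fish 4 highest for CUST_6681_PI428451953 at -5.90. The last 2 are among the 15 sets and compare background signals alone. Of the array measures, the median signal was lowest for brain of control fish 4 at 43.2 (nearest 110.9). The share of probes well above background was lowest for skin of control fish 7 at 65.6% (nearest 69.1%), and brain of transgenic fish 5 had 24 non-uniform spots (nearest 9).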

How the results depend on the processing

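The 24 values of named probes kept their direction in all 602 alternative values, and 600 of these stayed on the same side of the threshold. The exceptions were the tissue contrast of CUST_23803_PI428451953 (main 3.91), at 0.15 with normexp background correction (limma adjusted p = 0.744) and 0.59 with the authors' values (limma adjusted p = 0.293). The cause was not tested. The named probes were picked for large differences or small p on these same arrays, so steady directions and calls were likely from the outset. Sizes held less well. Of the 21 called values of named probes, all shrank on the log2 scale with normexp, to between 3.84% and 66.9% of the main value and 20 of them by over 1.5 times, and all 15 that have a lower bound fell under it, such as CUST_3609_PI428451958 in brain (11.11 to 5.74) and CUST_6682_PI428451953 in skin (-4.49 to -0.83). That setting adds an offset of 50 to every signal, which by construction shrinks differences from dim signals. The bounds therefore apply only to the scaled signals of the main setting, which have no offset. In the authors' values, which cover 11 of the 21, 9 shrank so, to between 15.09% and 87.1% over the 11, and all 6 with a bound fell under it; the cause was not tested. In the other settings no called value moved by over 1.5 times. No changed brain or skin probe was called in the opposite direction in any of the 27 alternatives per tissue that were compared probe by probe. The share of changed probes that rose went from 45.4% to 50.8% in brain (main 47.2%) and from 45.5% to 53.3% in skin (main 50.2%, median scaling 45.5%). Whether rises or falls prevailed therefore depended on the setting in both tissues. Apart from the values listed next and the leave-one-out fits, counts stayed within 1.5 times the main value: 2915 to 5432 for brain (main 3717), 8143 to 12451 for skin (main 9642), 2522 to 4386 for the difference between tissues (main 3040) and 1550 to 2175 for both tissues (main 1799). With slide as a fixed term 2003 brain and 5417 skin probes changed. On 2 of the 6 slides both arrays of a tissue were of one genotype, so that fit compares 8 arrays. Unadjusted p under 0.05 with at least a 2-fold change gave 2011 in brain and 4167 in skin, and an adjusted p under 0.1 gave 2708 in both tissues. Leaving out 1 fish gave 2842 to 3813 in brain, 7951 to 9547 in skin, 1944 to 3190 for the difference, lowest without control fish 3, and 1364 to 1714 for both. The replicate block by the 4 fish numbers that the genotypes share left 432 brain and 3083 skin probes. The same 8 arrays without the block, a fit added after seeing the data, gave 1346 and 4785. Same-numbered fish are different animals, and no fish correlated best with its own number. With fish as a replicate block across tissues, which pairs brain and skin, the difference was called for 3950 probes by per-fish differences and 4386 as a random block, which kept 2779 and 3040 of the 3040 calls. Scaling moved the median difference of all tested probes by less than 0.1. The gene-based alternatives were not run, as probes have no gene names here. Signal over background limits some of the largest falls and rises to lower bounds. Of the fitted 8-fold changes, 104 of 209 in brain and 110 of 301 in skin had 1 genotype not well above background on any array.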

Other observations

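The tests of the run of probe numbers were written before their results were seen, but the run itself was noticed in the data.

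Changes in brain were not spread evenly along the numbers in the probe names. In the larger probe set, 550 of 21048 probes tested in brain fell at least 2-fold (2.61%). Among 100 successive tested probes, numbered 18908 to 19044, 20 fell so and 4 rose so, where the highest window in 1000 shuffled orders held 14 falls. The shuffles take neighbouring numbers as independent. Some neighbours are not, such as CUST_6681_PI428451953 and CUST_6682_PI428451953, which had similar signals wherever they were well above background. Such neighbours make runs likelier than in a shuffled order, so the shuffles do not show that this run is unusual. Of the 20 probes, 15 were not well above background on any transgenic brain array, and with such signals set at the floor their median fall in brain was at least 15.7-fold. All 19 that were tested in skin fell there too, and 3 of them were not well above background on any transgenic skin array. With signals under the floor set at it, the median fall in skin was at least 4.09-fold. A defect at one place on the arrays would put the 20 spots close together, but their median distance was 1383 scanner pixels, with 1278 at the lowest 5% of random sets. Across the 6 control fish the 20 probes had a median pairwise correlation of 0.871, against 0.162 at the 95th percentile of random sets of other fallen probes. Across the 6 transgenic fish, where most of them were at background, it was 0.169. This may come from transcripts that vary together or from one transcript seen by many probes; which of these holds was not tested, as the probes have no gene names here.

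In skin, component 2 held 13.1% of the variance. Its scores were 71, 37, 58, -53, -56.9 and -46.5 for control fish 2, 3, 4, 5, 7 and 8, and 17.8, 17.9, 21.6, -9, -30.4 and -27.5 for transgenic fish 1, 2, 4, 5, 6 and 7. In each genotype 3 fish were above 0 and 3 below, and each group held 3 males and 3 females. The fish above 0 had the lower numbers in each genotype. Whether the scores follow sex, or anything else that goes with the numbers, was not tested. In brain, component 2 held 14.9%, with the lowest scores for control fish 4 at -90 and transgenic fish 6 at -55.5. These 2 brain arrays shared a slide and had the lowest median signals in brain, at 43.2 and 63.4. Whether the scores follow slide or signal was not tested.

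The share of brain probes that changed was 14.7% in signal quartile 1, the dimmest, and 7.92% in quartile 4, the brightest. In skin the values were 32.3% and 32.7%. The median residual SD was 0.45 and 0.197 in these quartiles of brain, and 0.502 and 0.268 in skin.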
